A study of Mus musculus with 12 samples.

How the data were processed

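Per the labels, isolated optic nerves of male C57Bl/6 mice were left as controls or exposed to oxygen-glucose deprivation (OGD), alone or together with the drug CX-4945 or MS-275. Small RNA was then profiled on an nCounter miRNA panel, which counts fluorescent barcodes bound to each target without amplification. The 12 samples fall into 4 groups of 3, read from the agent field of the labels. Doses, durations, the order of drug and OGD, the panel version and the number of nerves or animals per sample are not given in the sources used here. Per the file headers, each column of the main table comes from one nCounter lane file, and its values are the deposited raw barcode count of each probe in that lane. The values were whole numbers with a different total in each lane.

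The table held 566 mouse miRNA probes, 33 viral miRNA probes, 6 positive controls, 8 negative controls, 6 ligation controls (3 of them positive), 4 mRNA probes and 3 spike-in probes. The total count over the miRNA probes ran from 254692 to 542399 per lane. The spike-in probes reached at most 12 counts in any lane, so no spike-in scaling was run. 1 row without a probe name was left out. The limit of detection of a lane was the mean plus 2 SD of its negative controls and lay between 32.0 and 60.6 counts. A probe was tested when its count exceeded that limit in at least 3 of the 12 lanes, which left 217 probes, 150 of them above the limit in every lane. The probes that were not tested held 1.21% of the miRNA count summed over the 12 lanes, and 333 probes never exceeded the limit.

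A second table held the deposited processed signal of each probe, whose making is not stated by the authors. Set against the raw counts, values over 20 followed the count minus the median of the 8 negative controls, times a factor from the mean of the 4 mRNA probes. The median ratio of deposited to rebuilt values was 1.001 in every lane, and the largest difference among values over 20 was 0.0154 after that ratio. Between 238 and 362 probes per lane stood at a lowest value of 1 to 1.44, to which the rule does not apply, and values between that and 20 were not compared in the same way. These signals were used only as an alternative, on a log2(value + 1) scale. The probe annotation is that of the files. Of the 217 tested probes, 204 had a gene of their name in the RefSeq table of assembly GRCm38.p6, which was used only for names, and 13 did not. What those 13 measure was not checked. 5 tested probes named more than 1 miRNA and cannot separate them, and closely related members of a family, such as those of let-7, can share signal.

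The main test was edgeR's quasi-likelihood test (version 4.0.16 in R 4.3.3) on the raw counts with TMM factors and robust dispersion. All 12 samples entered one fit with a mean per group, and Benjamini-Hochberg adjustment ran over the 217 probes with a threshold of 0.05. The comparisons were OGD vs Control, each drug group vs OGD, each drug group vs Control, the drug groups against each other, the mean of both drug groups vs OGD, and any difference among the 4 groups. Normalised counts in the text are TMM-scaled and given as mean ± SD with n = 3 per group, and log2 fold changes carry the standard error (SE) of the fit. Exact permutation tests compared lane measures between groups, where 3 samples against 3 allow no two-sided p below 0.10. The common biological coefficient of variation was 16.6%. Between replicate lanes the squared differences were at least 9.93 times those of counting error, so counting depth was not what limited the precision. A lower count of detected probes in a lane still limits miRNAs near the background.

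Before the data were examined, 22 lists of miRNAs were fixed from general knowledge, together with the tests, the alternatives and the rule for named miRNAs. The lists were oligodendrocyte lineage, astrocyte-associated, microglia and leukocyte, vascular and mesenchymal, erythroid, skeletal muscle, neuron, retina and pigment epithelium, epithelium, hypoxia, inflammatory response, p53-induced, the miR-15/16, let-7, miR-30 and miR-181 families, the miR-17-92 cluster and its paralogs, the miR-23/27/24 clusters, the Dlk1-Dio3 cluster, the Sfmbt2 cluster, an X-linked germline cluster and viral probes. The 18 lists with at least 3 tested members were tested with limma's camera (version 3.58.1) at its preset correlation, with camera at an estimated correlation, and with fry, each adjusted by Benjamini-Hochberg over the 18 lists. camera asks whether a list moved relative to the other probes, and fry whether its members on balance moved one way. Some lists share members: miR-23a, miR-146a and miR-146b each stand in 2.

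The rule for named miRNAs took the 10 smallest unadjusted p-values in each direction for OGD vs Control and for each drug vs OGD, and the 3 smallest in each direction for the other comparisons. It took only miRNAs above the limit in all 3 samples of the higher group, whether or not they passed the threshold. It added up to 4 list members per list past the threshold, up to 10 miRNAs past the threshold with opposite signs in OGD and drug comparisons, and miR-210, miR-219, miR-338-3p, miR-21, miR-146a, miR-155, miR-124 and miR-34a wherever tested. miR-155 was on the panel but below the limit of testing. miRNAs outside this rule were named after their values were seen: those past the threshold adjusted over their list alone, those past it in DESeq2, those with an unadjusted p under 0.05 in 2 comparisons, miR-486, and miR-2133, miR-2134, miR-2140 and miR-2141 together.

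The scripts were tested on simulated data with the lanes' own means, totals and dispersions, in 20 simulations per fold size with 40 of the 217 probes changed. For OGD vs Control, 34.3% of probes changed 1.5-fold were recovered, 90.8% at 2-fold and 98.8% at 3-fold. The shares were 40.8%, 90.0% and 99.1% for OGD+CX-4945 vs OGD, and 29.5%, 92.9% and 98.8% for OGD+MS-275 vs OGD. Of the probes called in these runs, the share that had not been changed lay between 2.55% and 6.80%. The Dlk1-Dio3 list was found by camera in 100% of 20 simulations with all 27 members changed 1.2-fold and in 0% with no change, but these simulations hold no correlation between miRNAs.

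The alternatives were DESeq2 (version 1.42.0), DESeq2's size factors in edgeR, scaling by the 100 most abundant miRNAs, by the positive controls, by the mRNA probes or by the ligation controls, no filter, only probes above the limit in all lanes, background subtraction with limma-trend, limma-voom, the deposited processed signals with limma, only the compared groups in the fit, no robust dispersion, each sample left out in turn, and the title-number sets as a block of 3 or of 2 sets. The sample titles carry a number whose first 3 digits are 107, 113 or 114 and a suffix from 1 to 12, and the labels do not say what either means. Control, OGD and OGD+CX-4945 hold 1 sample of each set, and OGD+MS-275 holds 2 of set 107 and 1 of set 113. The suffix runs from 1 to 3 in Control, 4 to 6 in OGD, 7 to 9 in OGD+CX-4945 and 10 to 12 in OGD+MS-275. Whatever follows its order therefore cannot be told apart from the groups. Further alternatives were chosen after seeing the data: the ligation control count as a covariate, the order of the suffix within a group as a block, the title-number sets together with the ligation covariate, the 13 probes without a RefSeq gene left out, and the 2 lanes with the lowest ligation counts of the OGD and OGD+CX-4945 groups left out. Replicate numbers 1 to 3 in the text follow the order of the samples in the labels. The labels do not say that the samples came from separate animals, so all p-values measure the spread between these samples only.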

Results

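MicroRNAs of the isolated mouse optic nerve, a white-matter tract of axons, glia and vessels, were counted in 4 groups: untreated nerves (Control), nerves under oxygen-glucose deprivation (OGD), and nerves under OGD with CX-4945 or with MS-275. CX-4945 (silmitasertib) inhibits casein kinase 2, and MS-275 (entinostat) inhibits class I histone deacetylases. Each group had 3 samples, and values with ± are means and SD of 3. The total miRNA count per lane was 326156 ± 41815 in Control, 343762 ± 81989 in OGD, 423736 ± 102912 in OGD+CX-4945 and 414098 ± 67354 in OGD+MS-275. Between 154 and 224 mouse miRNA probes per lane exceeded the lane's background limit, with the lowest number in OGD replicate 2. None of the 33 viral probes exceeded it in any lane, and 0 of the 23 probes of the X-linked germline cluster reached the minimum for testing.

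The glial miRNAs miR-338-3p and miR-219 and the neuronal miR-124 passed the threshold in no comparison. miR-338-3p, which promotes oligodendrocyte differentiation, had normalised counts of 19476 ± 200 in Control, 20903 ± 973 in OGD, 20261 ± 3006 in OGD+CX-4945 and 18985 ± 2157 in OGD+MS-275. miR-219, of the same lineage, had 12519 ± 2509, 11074 ± 2123, 9646 ± 2218 and 11044 ± 2874 in the same order, and the neuronal miR-124 7886 ± 201, 7819 ± 438, 7721 ± 678 and 7480 ± 512. The 10 most abundant probes took between 46.4% and 50.7% of a lane's miRNA count. The 3 positive ligation controls, which report how well a tag was joined to small RNA in a lane, differed between lanes by up to 3.41-fold. Their geometric mean was 1726 ± 558 counts in Control, 1761 ± 657 in OGD, 2749 ± 1061 in OGD+CX-4945 and 3020 ± 123 in OGD+MS-275, where all 3 lanes lay above every Control and OGD lane (exact permutation test, two-sided p = 0.10 against either group, the smallest that 3 against 3 allows; Benjamini-Hochberg adjusted p = 0.491 over 54 tests). Over the 12 lanes, log2 ligation counts correlated with the first principal component of the tested miRNAs, which held 40.4% of the variance (Pearson r = 0.926, permutation p = 6.0e-05; Spearman rho = 0.888, permutation p = 2.1e-04). With group means removed r was 0.900 (permutation p = 8.0e-05) and rho 0.860 (permutation p = 6.2e-04). Without the 2 farthest lanes r was 0.906 over all lanes and 0.798 with group means removed, and the Benjamini-Hochberg value over 6 relations was 2.4e-04 for both.

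**Figure D1:**
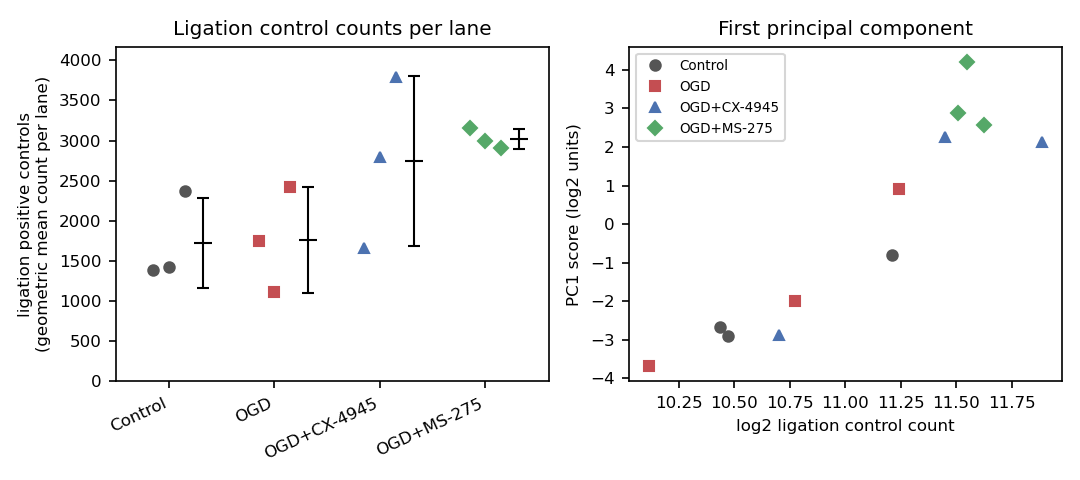
Left, geometric mean count of the 3 positive ligation controls in each lane, by group, with mean and SD (black); right, the first principal component score of each lane against its log2 ligation control count. The 3 OGD+MS-275 lanes lie between 2914 and 3155 counts, and r between score and ligation count is 0.926 over 12 lanes.

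OGD was compared with untreated nerves to see what deprivation changes. let-7 members and miRNAs of red blood cells were among those with lower means than in Control. let-7c, of the let-7 family that promotes differentiation, had 9799 ± 1448 normalised counts in OGD against 13393 ± 1092 in Control (log2 fold change -0.45, SE 0.14), let-7a 6142 ± 1158 against 8170 ± 686 and let-7f 2029 ± 366 against 2686 ± 33.4. miR-144 and miR-451, made from one erythroid transcript, had 75.3 ± 12.01 against 113.4 ± 17.2 and 879 ± 92.3 against 1230 ± 62.2. miR-210, a target of hypoxia-inducible factor, had 394 ± 27.8 counts against 356 ± 24.4 (log2 fold change 0.14, SE 0.16). No single miRNA passed the threshold.

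By list, the erythroid miRNAs were lower in OGD than in Control, with a median log2 fold change of -0.48 and all 3 members lower (camera adjusted p = 0.0203; adjusted p = 0.442 with an estimated correlation; fry adjusted p = 0.284). 0 of the 3 passed over all probes and 2, miR-144 and miR-451, adjusted over the list alone. In each of the 3 OGD lanes the median of the list lay below that of every Control lane. The call was lost without Control replicate 2 (adjusted p = 0.0682), OGD replicate 2 (0.167) or OGD replicate 3 (0.0588), and when scaled by the mRNA probes (0.0661). Of the 9 let-7 family probes 6 were lower (median -0.05, mean -0.14; camera adjusted p = 0.270), and 1, let-7c, passed adjusted over the list alone. The glial lists had medians of 0.10 (oligodendrocyte lineage), -0.15 (astrocyte-associated) and -0.03 (microglia and leukocyte). The vascular and mesenchymal list had -0.13, with the smooth-muscle miR-145 at 1016 ± 71.2 against 1451 ± 458 counts. All 5 members of the miR-15/16 family (median 0.12), all 7 of the miR-17-92 cluster and paralogs (0.08) and all 5 of the miR-23/27/24 clusters (0.10) had higher means, with camera adjusted p-values of 0.368, 0.567 and 0.368. The other medians were -0.10 for skeletal muscle, -0.05 for neuron, -0.07 for epithelium, 0.02 for inflammatory response, 0.09 for p53-induced, 0.04 for the miR-30 family, 0.04 for the miR-181 family, -0.08 for the Dlk1-Dio3 cluster and -0.14 for the Sfmbt2 cluster, where 1 of 8, miR-669f, passed adjusted over the list alone. miR-204, the only tested member of the retina and pigment epithelium list, had -0.07. No other member of these lists passed, over all probes or adjusted over its list alone.

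Among the 20 miRNAs taken by smallest p, the lower ones also included miR-669f (-0.52, SE 0.16), miR-1937a+miR-1937b (-0.63, SE 0.22), miR-328 (-0.54, SE 0.19) and miR-221 (-0.48, SE 0.22). The higher ones included miR-331-3p (176 ± 27.1 against 141 ± 11.7), miR-194 (76.3 ± 9.94 against 59.6 ± 1.11), miR-27b (215 ± 7.19 against 173 ± 16.7), miR-425 (232 ± 11.7 against 196 ± 6.64) and miR-16 (13004 ± 1177 against 11545 ± 964). miR-376a, miR-2140, miR-1839-5p, miR-26a and miR-103 completed the higher ones, with log2 fold changes of 0.31, 0.79, 0.24, 0.25 and 0.22. The inflammation-related miR-21 (0.11, SE 0.21) and miR-146a (-0.07, SE 0.15) and the p53 target miR-34a (-0.17, SE 0.24) had values within 1 SE of 0. edgeR's quasi-likelihood test called 0 of 217 probes (lowest Benjamini-Hochberg adjusted p = 0.430), as did DESeq2 and limma-voom. An unadjusted p under 0.05 was found for 12 probes in edgeR, 10 in DESeq2 and 12 in limma-voom, where 10.9 come by chance. Of edgeR's, 11 were lower and 1 higher, miR-146b (0.55, SE 0.26), named after its values were seen. The 12 became 7 without Control replicate 2 and 7 without OGD replicate 2. miR-146b lay near or below the mean background limits of 33.1 counts in Control and 51.1 in OGD. The negative controls were 1.47 times as high in OGD as in Control, and the main test does not subtract background. The groups did not overlap for 30 probes, 13.8% of those tested, where chance gives 10%. For 205 probes the 95% interval excluded a 2-fold change in either direction.

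Nerves under OGD with CX-4945 were compared with nerves under OGD alone. The miRNAs of the Dlk1-Dio3 cluster, a large imprinted cluster expressed from the maternal chromosome, stood higher with the drug. 24 of its 27 tested members had a higher mean, with a median log2 fold change of 0.28. miR-127 had 272 ± 75.4 normalised counts against 184 ± 28.0, miR-410 457 ± 91.0 against 343 ± 51.9, miR-376a 296 ± 56.7 against 223 ± 47.4 and miR-376b 427 ± 137 against 310 ± 38.7. let-7c had 12667 ± 1176 against 9799 ± 1448 (log2 fold change 0.37, SE 0.14). No single miRNA passed the threshold.

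camera gave the Dlk1-Dio3 list an adjusted p = 1.7e-04, and adjusted p = 0.982 with an estimated correlation (fry adjusted p = 0.969); 0 of its members passed, over all probes or adjusted over the list alone. Without OGD replicate 3 its camera adjusted p was 0.112, and without OGD+CX-4945 replicate 2 the median was 0.12 (adjusted p = 0.851). With the title-number block of 3 sets and the ligation covariate together the median was 0.03 (camera adjusted p = 0.908). Scaled by the ligation controls the median was -0.01, where the median of all probes was -0.26. No other list passed, and no member of one passed adjusted over its list alone. The neuron list had a median of 0.20, with miR-218 at 645 ± 209 against 467 ± 54.9 counts and miR-128 at 118 ± 21.8 against 147 ± 18.5. Medians above 0 were also those of astrocyte-associated (0.16), p53-induced (0.09), let-7 family (0.09), miR-30 family (0.05), inflammatory response (0.03) and vascular and mesenchymal (0.02). Those below 0 were skeletal muscle (-0.18), epithelium (-0.12), miR-23/27/24 clusters (-0.08), miR-15/16 family (-0.07), oligodendrocyte lineage (-0.05), erythroid (-0.05), miR-17-92 cluster and paralogs (-0.05), microglia and leukocyte (-0.04) and miR-181 family (-0.01), and that of the Sfmbt2 cluster was within 0.01 of 0. miR-210, of the hypoxia list, had -0.11 and miR-204 -0.11.

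Higher means with CX-4945 were also those of miR-1937a+miR-1937b (633 ± 105 against 404 ± 90.2), miR-1937c (417 ± 104 against 278 ± 41.9), miR-328 (181 ± 36.8 against 131 ± 35.7) and miR-433 (515 ± 128 against 384 ± 47.1). Lower means were those of miR-27a (6214 ± 1284 against 8276 ± 1786), the lymphocyte miRNA miR-150 (1802 ± 273 against 2317 ± 375) and miR-33, which lies in a sterol regulator gene and represses cholesterol export (168 ± 20.9 against 215 ± 15.1). miR-362-3p, miR-190, miR-99a, miR-30c, miR-194 and miR-22 had log2 fold changes of -0.36, -0.49, -0.29, -0.31, -0.34 and -0.28. In the fit with the ligation covariate, miR-27a, miR-150, miR-99a, miR-30c and miR-22 fell with the ligation count within groups. Each slope had an edgeR adjusted p under 0.05, and those of miR-33, miR-362-3p, miR-190 and miR-194 did not pass. Mean ligation counts were 2749 with CX-4945 and 1761 in OGD. For miRNAs with such a slope, ligation yield and the drug cannot be told apart. miR-219 (-0.20, SE 0.21), miR-338-3p (-0.04, SE 0.12), miR-124 (-0.02, SE 0.11), miR-21 (-0.03, SE 0.21), miR-146a (0.10, SE 0.15) and miR-34a (0.09, SE 0.23) had values within 1 SE of 0. edgeR's quasi-likelihood test called 0 probes (lowest Benjamini-Hochberg adjusted p = 0.448), as did DESeq2 and limma-voom. An unadjusted p under 0.05 was found for 16 probes in edgeR, 11 higher and 5 lower, and for 14 in DESeq2 and 14 in limma-voom. The 16 became 5 without OGD+CX-4945 replicate 2, 6 without OGD replicate 2, 10 without OGD replicate 1 and 31 without OGD+CX-4945 replicate 1. The groups did not overlap for 14 probes (6.45%; chance 10%), and for 205 the 95% interval excluded a 2-fold change.

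Nerves under OGD with MS-275 were compared with nerves under OGD alone. miR-2133 rose from 27.2 ± 5.40 normalised counts in OGD to 73.9 ± 0.804 with the drug, in all 3 samples (log2 fold change 1.44, SE 0.28; edgeR adjusted p = 0.0264). Its raw counts were 17 to 31 in the OGD lanes, below the background limit in all 3, and 72 to 98 in the OGD+MS-275 lanes, above it in all 3, so the fold rests on background counts in OGD. miR-2133, like miR-2134 and miR-2141, has no RefSeq gene of its name. miR-2141 (1587 ± 622 against 513 ± 118; 1.63, SE 0.39) and miR-2134 (255 ± 30.1 against 76.1 ± 46.2; 1.71, SE 0.49) also had higher means and did not pass. miR-338-5p, from the other strand of the oligodendrocyte miRNA precursor, had 87.2 ± 9.03 against 57.8 ± 7.99 counts (0.59, SE 0.16) and did not pass over all probes. Its raw counts in OGD were 37 to 62, above the background limit in 2 of 3 lanes.

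The Dlk1-Dio3 list stood higher with MS-275, with a median of 0.28 and 23 of 27 members higher (camera adjusted p = 0.0157; adjusted p = 0.890 with an estimated correlation; fry adjusted p = 0.649). In OGD+MS-275 replicate 2 the median difference of the list from the Control mean was -0.09, below every OGD lane, and without that lane the log2 fold change had a median of 0.42. miR-376b had 480 ± 17.6 against 310 ± 38.7 counts, miR-487b 414 ± 106 against 265 ± 40.9 and miR-127 274 ± 49.2 against 184 ± 28.0; 0 of the 27 passed, over all probes or adjusted over the list alone. The call was lost without OGD replicate 3 (adjusted p = 0.258), OGD+MS-275 replicate 1 (0.373) or OGD+MS-275 replicate 3 (0.260) and when scaled by the mRNA probes (0.215). It was also lost with the title-number block of 3 sets (camera adjusted p = 0.418) or of 2 sets (0.0727). With the block of 3 sets and the ligation covariate together the median was -0.16. Scaled by the ligation controls the median was -0.18, where the median of all probes was -0.42. In the neuron list (median 0.29, 5 of 8 higher, camera adjusted p = 0.625), 0 passed over all probes and 3 adjusted over the list alone: miR-153 (52.5 ± 6.59 against 30.0 ± 8.58), miR-129-5p (119 ± 8.56 against 78.7 ± 19.1) and miR-129-3p (2277 ± 107.5 against 1563 ± 324). The OGD mean of miR-153 lay below the mean background limit of the OGD lanes, 51.1 counts. 1 member each passed adjusted over the list alone in the oligodendrocyte lineage (miR-338-5p, list median 0.05), the miR-30 family (miR-30c, 5707 ± 339 against 8147 ± 1676, list median 0.22) and the miR-23/27/24 clusters (miR-27a, 5437 ± 333 against 8276 ± 1786, list median -0.03). miR-204 had 4427 ± 325 against 5403 ± 575 and an unadjusted p under 0.05. It is the only tested member of the retina and pigment epithelium list, so adjustment over the list changes nothing. All 3 epithelium members had lower means (median -0.39, camera adjusted p = 0.389). The other medians were 0.32 for astrocyte-associated, 0.00 for microglia and leukocyte, 0.12 for vascular and mesenchymal, 0.15 for erythroid, -0.23 for skeletal muscle, 0.11 for inflammatory response, 0.19 for p53-induced, -0.06 for the miR-15/16 family, -0.11 for the miR-17-92 cluster and paralogs, 0.01 for let-7, 0.08 for the miR-181 family and 0.13 for the Sfmbt2 cluster, none past the threshold. With the ligation covariate the medians were -0.09 for astrocyte-associated, -0.06 for the miR-30 family, -0.03 for p53-induced and -0.13 for epithelium. Those of the neuron and erythroid lists were 0.20 and 0.18. The hypoxia miRNA miR-210 had -0.09, SE 0.16.

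Lower means with MS-275 were also those of miR-99a (3748 ± 169 against 5214 ± 807), miR-22 (6656 ± 62.6 against 9178 ± 1996), miR-150 (1643 ± 155 against 2317 ± 375), let-7d (16114 ± 878 against 20247 ± 1426), the endothelial miR-126-3p (9538 ± 168 against 11960 ± 1042), miR-15a (-0.53, SE 0.21) and miR-190 (-0.54, SE 0.22). miR-328 had a higher mean (189 ± 10.6 against 131 ± 35.7). In the fit with the ligation covariate, miR-99a, miR-22, miR-150, miR-126-3p, miR-15a, miR-27a and miR-30c fell with the ligation count within groups. miR-129-3p rose with it. Each of these slopes had an edgeR adjusted p under 0.05, and those of let-7d, miR-190 and miR-204 did not pass. All 3 OGD+MS-275 lanes had higher ligation counts than every OGD lane. For miRNAs with such a slope, ligation yield and the drug cannot be told apart. miR-219 (0.00, SE 0.21), miR-124 (-0.06, SE 0.11), miR-21 (0.16, SE 0.21) and miR-34a (0.18, SE 0.23) lay within 1 SE of 0, and miR-338-3p (-0.14, SE 0.12) and miR-146a (0.20, SE 0.15) within 2 SE. edgeR's quasi-likelihood test called 1 probe, limma-voom the same 1 and DESeq2 2, miR-2133 and miR-2141. In edgeR 45 had an unadjusted p under 0.05, 24 higher and 21 lower, where 10.9 come by chance, and the groups did not overlap for 52 (23.96%; chance 10%). Without OGD replicate 2 the 45 became 17, without OGD+MS-275 replicate 1 26, and with the ligation covariate 13. Calls numbered 24 with the title-number block of 3 sets, 7 when scaled by the mRNA probes and 5 when scaled by the positive controls. The call of miR-2133 was lost when scaled by the ligation controls, with background subtraction, with the ligation count as a covariate, an alternative chosen after seeing the data, and without any 1 of the samples compared except OGD replicate 3; without OGD+MS-275 replicate 1, miR-2141 passed instead.

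**Figure D2:**
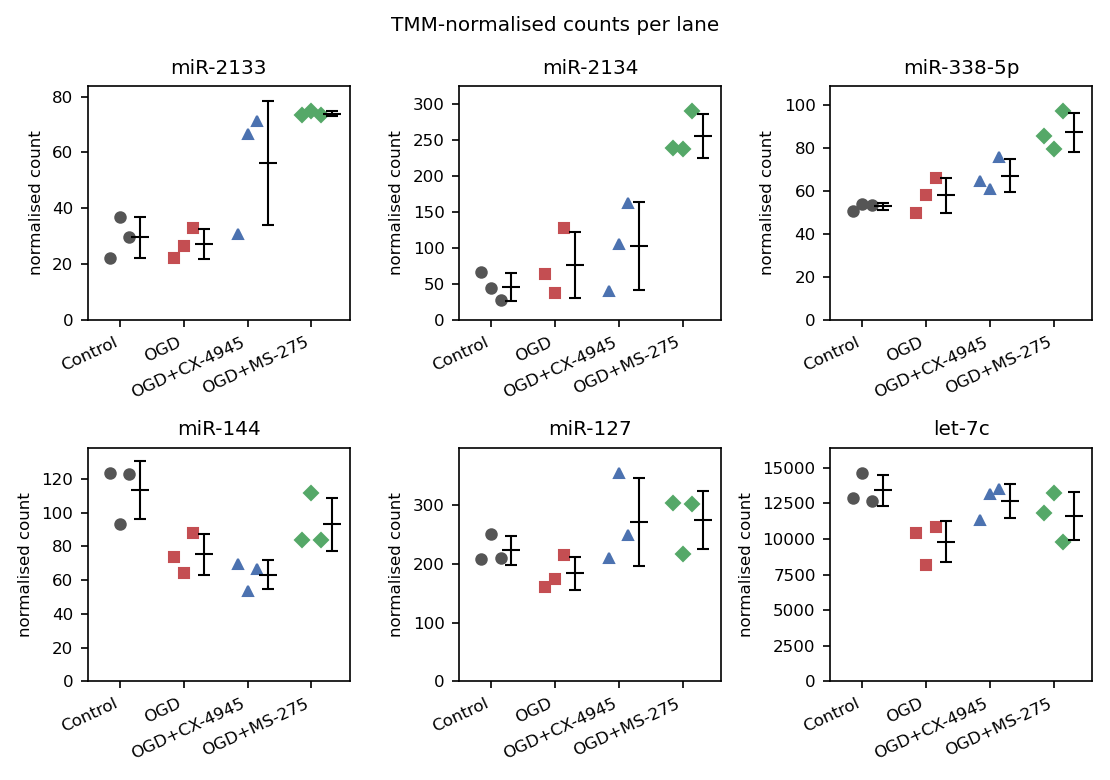
TMM-normalised count of 6 miRNAs in each of the 12 lanes, by group, with the mean and SD of each group in black; the vertical axes start at 0 and differ between panels. miR-2133 averages 73.9 in OGD+MS-275 and 27.2 in OGD, and miR-144 averages 63.3 in OGD+CX-4945 and 113.4 in Control.

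Each drug group was also set against untreated nerves. With MS-275, 3 probes rose above Control. miR-2133 had 73.9 ± 0.804 against 29.6 ± 7.37 normalised counts (log2 fold change 1.32, SE 0.28). miR-2134 had 255 ± 30.1 against 46.3 ± 19.4 (2.48, SE 0.52) and miR-338-5p 87.2 ± 9.03 against 52.7 ± 1.68 (0.72, SE 0.17). Each of the 3 had an edgeR adjusted p = 0.0497, with all 3 treated lanes above all 3 Control lanes. miR-2133 and miR-2134 have no RefSeq gene of their name, and what they measure was not checked. miR-2133 was below the background limit in all 3 Control lanes (raw counts of 17 to 29) and miR-2134 in 1 of them (27 to 51). miR-338-5p was above the limit in all 3 Control lanes but near it, with raw counts of 39 to 52 and limits of 32.0 to 33.7. The negative controls were 1.26 times as high in OGD+MS-275 as in Control, and the main test does not subtract background. miR-338-5p was the 1 member of the oligodendrocyte list to pass, over all probes and adjusted over the list alone, and miR-338-3p had -0.04, SE 0.12 and miR-219 -0.18, SE 0.21. miR-205, an epithelial miRNA, had 35.4 ± 2.10 against 62.1 ± 11.8, miR-22 6656 ± 62.6 against 9670 ± 790 and miR-99a 3748 ± 169 against 5190 ± 454, none past the threshold. miR-22 and miR-99a fell with the ligation count within groups (edgeR adjusted p under 0.05 for each slope), and the slope of miR-205 did not pass.

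No list passed camera for OGD+MS-275 vs Control, where the Dlk1-Dio3 list had a median of 0.12 (adjusted p = 0.181) and the erythroid list -0.29 (camera adjusted p = 0.440). All 5 p53-induced members had higher means (median 0.28; camera adjusted p = 0.195, fry adjusted p = 0.115), and 8 of 9 let-7 members lower ones (median -0.19; camera adjusted p = 0.181). Adjusted over the list alone, 2 neuron members passed with higher means, miR-129-3p (2277 ± 107.5 against 1364 ± 187) and miR-129-5p (119 ± 8.56 against 78.3 ± 9.65), and 2 vascular ones with lower means, miR-126-3p (9538 ± 168 against 12207 ± 1340) and miR-199a-3p (534 ± 46.6 against 786 ± 137). Others past the threshold in this way were miR-24 (0.44, SE 0.17) and miR-27a (-0.53, SE 0.17) of the miR-23/27/24 clusters, miR-195 (0.96, SE 0.29), miR-376a (0.71, SE 0.18), miR-205 (-0.80, SE 0.22) and miR-451 (-0.47, SE 0.17). miR-204 (-0.36, SE 0.12), the only tested member of its list, had an unadjusted p under 0.05, which adjustment over 1 member leaves unchanged. Within groups, miR-126-3p, miR-199a-3p and miR-27a fell with the ligation count and miR-129-3p rose, the directions given here. Each slope had an edgeR adjusted p under 0.05, and those of the others named in this way did not pass. The lower means, of miR-195 in Control and of miR-205 with MS-275, lay near or below the mean background limits there (33.1 and 46.7 counts). miR-21 (0.27, SE 0.21), miR-146a (0.13, SE 0.15), miR-124 (-0.08, SE 0.11), miR-210 (0.06, SE 0.16) and miR-34a (0.02, SE 0.23) did not pass. edgeR called 3 probes, DESeq2 12 and limma-voom 6; 50 had an unadjusted p under 0.05 in edgeR, 27 higher and 23 lower, and 62 (28.6%; chance 10%) had groups that did not overlap. With the ligation covariate, chosen after seeing the data, 0 passed and 21 had an unadjusted p under 0.05. Other settings gave more calls: 37 with the title-number block of 3 sets, and 19 with only the compared groups in the fit. The suffix-position block, also chosen after seeing the data, gave 33. With the block of 3 sets and the ligation covariate together 0 passed, and with background subtraction 0. Without any 1 of the samples compared none of the 3 passed; without OGD+MS-275 replicate 1, 2 others did, miR-2140 and miR-2141. Without Control replicate 2 the 50 became 28, and without OGD+MS-275 replicate 1 33. Without the 13 probes that have no RefSeq gene of their name, among them miR-2133 and miR-2134, 0 passed.

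With CX-4945, no miRNA passed against Control. The erythroid list stood lower, with a median of -0.53 and 2 of 3 members lower (camera adjusted p = 0.0205; adjusted p = 0.590 with an estimated correlation; fry adjusted p = 0.206). miR-144, at 63.3 ± 8.39 against 113.4 ± 17.2 counts, had a log2 fold change of -0.84, SE 0.18 (edgeR adjusted p = 0.0678; all 3 lanes below Control), and miR-451 -0.53, SE 0.17; both passed adjusted over the list alone, and miR-486 had 0.09, SE 0.19. The erythroid call was lost without Control replicate 2 (adjusted p = 0.0778) or 3 (0.0853), without OGD+CX-4945 replicate 2 (0.222) or 3 (0.0806), and with the ligation covariate (median -0.43, adjusted p = 0.155). The Dlk1-Dio3 list stood higher, with a median of 0.15 and 24 of 27 members higher (camera adjusted p = 0.0205; adjusted p = 0.934 with an estimated correlation; fry adjusted p = 0.911). 1 member, miR-376a (296 ± 56.7 against 181 ± 18.6; 0.71, SE 0.18), passed adjusted over the list alone, and miR-434-3p had 969 ± 193 against 649 ± 126. That call was lost without Control replicate 2 (adjusted p = 0.116) or 3 (0.565), without OGD+CX-4945 replicate 1 (0.0733) or 2 (0.891) and with no filter (0.134). With the title-number block of 3 sets and the ligation covariate together the median was -0.07 (camera adjusted p = 0.591). Single lanes moved the median: it was 0.00 without OGD+CX-4945 replicate 2, 0.04 without Control replicate 3, 0.08 without Control replicate 2, 0.27 without Control replicate 1 and 0.31 without OGD+CX-4945 replicate 3. Scaled by the ligation controls its median was -0.07, where the median of all probes was -0.19. In the Sfmbt2 cluster (median -0.11) 2 passed adjusted over the list alone, miR-669f (-0.52, SE 0.16) and miR-466g (0.71, SE 0.23). miR-33 (168 ± 20.9 against 240 ± 21.5) and miR-331-3p (195 ± 31.8 against 141 ± 11.7) did not pass. edgeR called 0 probes (lowest adjusted p = 0.0678), limma-voom 0 and DESeq2 2, miR-144 and miR-376a; 18 had an unadjusted p under 0.05 in edgeR, 10 higher and 8 lower, 17 in DESeq2 and 18 in limma-voom. The groups did not overlap for 17 probes (7.83%; chance 10%). Without OGD+CX-4945 replicate 1, 6 probes passed, and without Control replicate 2, 1. The 18 became 38 and 11 without these lanes.

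**Figure D3:**
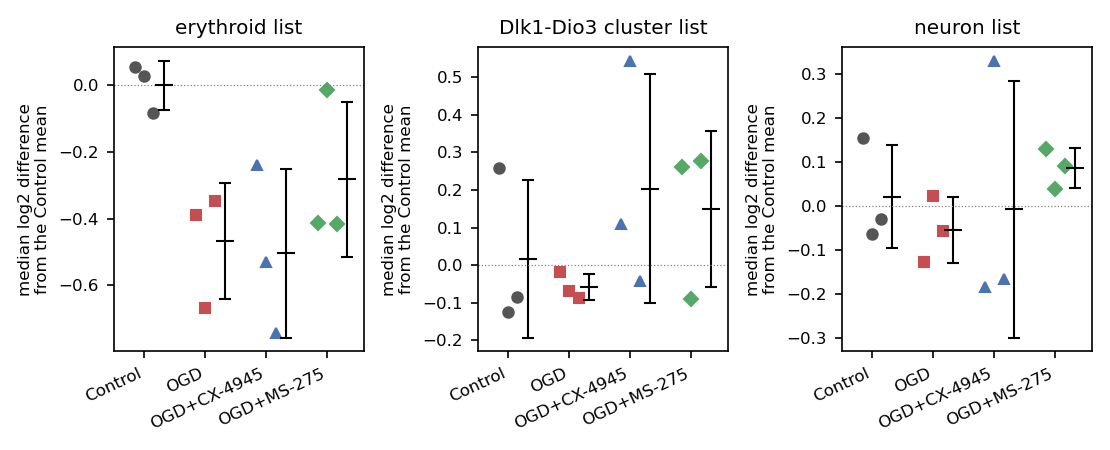
Median log2 difference from the Control mean over the members of the erythroid (3 miRNAs), Dlk1-Dio3 (27) and neuron (8) lists in each of the 12 lanes, by group, with the mean and SD of each group in black. The erythroid medians lie between -0.67 and -0.35 in OGD and between -0.08 and 0.06 in Control, and the Dlk1-Dio3 medians reach 0.54 in OGD+CX-4945.

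The drug groups were tested directly against each other. miR-144 (63.3 ± 8.39 against 93.0 ± 15.9 counts), miR-2134 (103 ± 61.2 against 255 ± 30.1), miR-669f (70.1 ± 10.02 against 92.5 ± 2.33) and miR-338-5p (66.9 ± 7.69 against 87.2 ± 9.03) had lower means with CX-4945 than with MS-275. miR-720, since recognised as a tRNA fragment (20468 ± 6085 against 15388 ± 2699), let-7d (0.24, SE 0.12) and miR-1198 (0.40, SE 0.20) had higher means. None passed over all probes; miR-144 passed adjusted over the erythroid list alone. No list passed: the p53-induced list (median -0.16, all 5 lower) had a camera adjusted p = 0.0951 and the let-7 family (median 0.13, 7 of 9 higher) a camera adjusted p = 0.0708. edgeR called 0 probes (lowest adjusted p = 0.920), as did DESeq2 and limma-voom, and an unadjusted p under 0.05 was found for 9, 7 and 10, where 10.9 come by chance. The 9 became 4 without OGD+CX-4945 replicate 1, 19 without OGD+CX-4945 replicate 2, 15 without OGD+CX-4945 replicate 3 and 3 without OGD+MS-275 replicate 3. The groups did not overlap for 19 probes (8.76%; chance 10%). For 208 of 217 probes the 95% interval of the difference excluded a 2-fold change in either direction.

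The mean of the drug groups was set against OGD for what both have in common. miR-2133 rose (log2 fold change 1.26, SE 0.26, edgeR adjusted p = 0.0421). Its raw counts were 29 to 101 with CX-4945, where 2 of 3 lanes exceeded the background limit, and 72 to 98 with MS-275, where all 3 did. In OGD they were 17 to 31, below the limit in all 3 lanes, so the fold rests on background counts in OGD. The Dlk1-Dio3 list stood higher, with 25 of 27 members higher and a median of 0.29 (camera adjusted p = 0.00120; adjusted p = 0.961 with an estimated correlation; fry adjusted p = 0.779). miR-127 (0.57, SE 0.18), miR-328 (0.49, SE 0.17) and miR-2141 (2.30-fold) had higher means and miR-27a (-0.51, SE 0.14), miR-150 (-0.43, SE 0.14) and miR-99a (-0.38, SE 0.12) lower ones, none past the threshold. Adjusted over their lists alone, miR-27a and miR-30c (-0.41, SE 0.14) passed. miR-27a, miR-150, miR-99a and miR-30c fell with the ligation count within groups (edgeR adjusted p under 0.05 for each slope). edgeR called 1 probe, DESeq2 2 and limma-voom 0, and 35 had an unadjusted p under 0.05 in edgeR, 23 higher and 12 lower (11 without OGD replicate 2, 53 without OGD+CX-4945 replicate 1, 16 with the ligation covariate). The Dlk1-Dio3 call was lost without OGD replicate 3 (adjusted p = 0.218) and with the title-number block of 3 sets (median 0.22, camera adjusted p = 0.0537). With that block and the ligation covariate together the median of the list was -0.09. Scaled by the ligation controls its median was -0.11, where the median of all probes was -0.33 and the list passed. Without OGD+CX-4945 replicate 2 its median was 0.19. Without OGD+CX-4945 replicate 1, 11 probes passed, and without any 1 of the other samples compared, 0. The test of any difference among the 4 groups called 1 probe, miR-2133 (edgeR adjusted p = 0.0416), with 33 at an unadjusted p under 0.05 (19 without Control replicate 2, 22 without OGD+MS-275 replicate 1).

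Fold changes of the drugs were set against those of OGD over the 217 probes, which are not independent replicates, to see whether the drugs turned back what OGD had moved. 4 miRNAs had an unadjusted p under 0.05 both in OGD vs Control and in OGD+CX-4945 vs OGD, all lower in OGD and higher with the drug: let-7c, miR-1937a+miR-1937b, miR-328 and miR-221. For MS-275 there were 2 of this kind, miR-328 (-0.54 and 0.52) and miR-669f (-0.52 and 0.39). 0 had the same sign in both, for either drug, and independent sets would share 0.581 and 1.31 of opposite sign. Unchanged groups simulated with the shared OGD samples, a simulation added after seeing the data that leaves out the correlation between miRNAs, shared 2.30 and 2.38 of opposite sign on average, and up to 5 and 5.53 in 97.5% of sets, so the 4 and 2 lie within what no change gives. None passed in both after adjustment. The correlation of log2 fold changes, from group means of log counts, was -0.373 for CX-4945 and -0.146 for MS-275, and unchanged groups simulated with the shared OGD samples gave -0.513 and -0.514. The covariance was -0.0190 and -0.0117 against simulated -0.0278 and -0.0279. When whole lanes were resampled, which keeps the correlation between miRNAs, 95% of unchanged sets gave between -0.912 and 0.543, and between -0.898 and 0.242. With edgeR's fold changes the correlations were -0.365 and -0.138.

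The fold changes of both drugs against OGD were compared in the same way. 10 miRNAs had an unadjusted p under 0.05 with both, each in the same direction: miR-127, miR-218, miR-328, miR-376a, miR-376b, miR-410 and miR-2133 were higher, and miR-27a, miR-150 and miR-190 lower. Independent sets would share 1.70, and unchanged groups with shared OGD samples, simulated in the same way, 2.41 on average (up to 5.53 in 97.5% of sets). Part of the excess may come from the shared OGD samples and from the correlation between miRNAs. Both drug groups also had higher mean ligation counts than OGD (1.56 times with CX-4945, 1.71 with MS-275) and Control (1.59 and 1.75). The simulated groups hold no such difference. miR-27a and miR-150 fell with the ligation count within groups (edgeR adjusted p under 0.05 for each slope). The slopes of the other shared miRNAs did not pass. How much of the excess comes with ligation yield was not tested. The sign was the same for 84.3% of the probes, and for 68.2% in unchanged groups with shared OGD samples. The correlation was 0.771 against a simulated 0.534 (0.795 with edgeR's fold changes), and the covariance 0.0637 against 0.0286. Against Control, 12 miRNAs had an unadjusted p under 0.05 with both drugs, all in the same direction, where such unchanged groups shared 2.05 on average (up to 5), and the correlation was 0.825 against a simulated 0.527, the covariance 0.0822 against 0.0275. With whole lanes resampled, unchanged sets reached 0.907 against OGD and 0.931 against Control, so both correlations lie within what lanes of this spread gave without an effect.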

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

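The test with the ligation covariate, and the use of the title-number block, which was itself chosen before the data were seen, as a test of an explanation were chosen only after the results were seen; the test of ligation slopes was written before its result. The control probes and mRNA probes, which lie outside the miRNA comparisons, were screened for groups in which all 3 lanes lay above all 3 Control lanes. Of 21 comparisons over 7 measures, 7 were so, where chance gives 5% for each. All comparisons share the same 3 Control lanes, so the 7 are not independent of each other.

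The ligation controls were 1.75 times as high in OGD+MS-275 as in Control (3020 ± 123 against 1726 ± 558 counts, n = 3), and after division by the positive controls the groups were no longer separate (1.59 times). The negative controls, which measure background, were 1.47 times as high in OGD (22.2 ± 4.13 against 15.1 ± 0.451), 1.45 times in OGD+CX-4945 and 1.26 times in OGD+MS-275. Divided by the positive controls these stayed separate, at 1.28, 1.29 and 1.13 times. The positive controls were 1.14 times as high in OGD and 1.124 times in OGD+CX-4945. Gapdh was 1.30 times as high in OGD+CX-4945 (386 ± 35.6 against 297 ± 37.9) and not separate after division by the positive controls (1.16 times).

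The ligation counts bear on the 50 probes with an unadjusted p under 0.05 in OGD+MS-275 vs Control. Over the tested probes, the slope on ligation counts within groups correlated with that comparison's fold change at r = 0.588, and 9.65% of all reassignments of the ligation values within groups gave as much, above the 5% set beforehand. The title-number sets, uneven between these groups, do not account for the calls, since with the sets as a block 37 probes passed against 3 without. Ligation yield and the drug cannot be told apart for these probes, because the 3 OGD+MS-275 lanes all have high ligation counts. An effect of MS-275 on the tissue stays open and was not tested apart from it.

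For miR-2133, miR-2134, miR-2140 and miR-2141 the median log2 fold change in OGD+MS-275 vs Control was 1.59, and 0.94 with the ligation covariate (median SE 0.43). Each stayed above 0, at 0.82, 1.52, 1.07 and 0.78, and miR-2133 and miR-2134, the 2 of them past the threshold without the covariate, were not past it with it; all 4 had smaller folds and, for miR-2133 and miR-2141, larger SE. Ligation yield and the drug cannot be told apart for these 4 probes, since the value lies neither near 0 nor past the threshold. A biological difference between MS-275 and Control nerves stays open.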

How the results depend on the processing

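The tests with the ligation covariate, the suffix-position block, the block with the ligation covariate, the probes without a RefSeq gene left out, and the 2 lanes of lowest ligation counts left out were chosen only after the results were seen. OGD vs Control had 0 calls in every setting. Of the values for single miRNAs and lists, 97 lost their side of the threshold, 63 gained it, 19 reversed a direction and 3568 did none of these. Only values past the threshold in the main fit could lose it. Single miRNAs past it were 1 in OGD+MS-275 vs OGD, 3 in OGD+MS-275 vs Control and 1 for the mean of both drugs. These account for 63 of the 97 losses. Most values were not past the threshold in the main fit, so the 3568 do not measure how stable the calls were. A direction was given only to lists past the threshold and to miRNAs with an unadjusted p under 0.05; of the other 1828 miRNA values 6.24% changed sign. Values under another scaling, size factor, background subtraction or the deposited values were compared after the shift of the median of all probes was taken off. The calls of OGD+MS-275 vs OGD ranged from 0 to 24 and those of OGD+MS-275 vs Control from 0 to 37. Where a value below moved, the cause was not tested, except that settings with fewer probes or samples have less to test. Depth did not limit abundant miRNAs; a background limit of up to 60.6 counts limits those near it, such as miR-2133.

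DESeq2 called 2 probes in OGD+MS-275 vs OGD, 2 in OGD+CX-4945 vs Control, 12 in OGD+MS-275 vs Control, 2 for the mean of both drugs and 7 for any difference among the 4 groups. DESeq2 size factors in edgeR gave 1 in OGD+CX-4945 vs Control, and 0 for the mean of both drugs and for any difference. Scaling by the 100 most abundant miRNAs gave 0 for the mean of both drugs. Scaling by the positive controls gave 5 in OGD+MS-275 vs OGD, 2 for the mean of both drugs and 4 for any difference. Scaling by the mRNA probes gave 7 in OGD+MS-275 vs OGD, 1 in OGD+CX-4945 vs OGD+MS-275, 3 for the mean of both drugs, 4 for any difference, and 0 miRNA lists in OGD vs Control and in OGD+MS-275 vs OGD. Scaling by the ligation controls gave 0 in OGD+MS-275 vs OGD and for the mean of both drugs. No filter gave 1 in OGD+MS-275 vs Control, and 2, 3, 1, 2 and 4 lists in OGD vs Control, OGD+MS-275 vs OGD, OGD+CX-4945 vs Control, OGD+MS-275 vs Control and the mean of both drugs; the correlations of drug and OGD fold changes were -0.535 and -0.490, and that of both drugs 0.653. Probes above background in all 12 lanes gave 0 in OGD+MS-275 vs OGD, for the mean of both drugs and for any difference, and 0, 1 and 1 lists in OGD vs Control, OGD+CX-4945 vs Control and OGD+CX-4945 vs OGD+MS-275. Background subtraction gave 0 in OGD+MS-275 vs OGD, OGD+MS-275 vs Control, the mean of both drugs and any difference, with correlations of -0.745 and -0.626. limma-voom gave 6 in OGD+MS-275 vs Control, and 0 for the mean of both drugs and any difference. The deposited processed values gave 4 in OGD+MS-275 vs OGD, 3 for the mean of both drugs and 4 for any difference, with correlations of -0.554 and -0.392. Only the compared groups in the fit gave 3 in OGD+MS-275 vs OGD, 19 in OGD+MS-275 vs Control and 0 for the mean of both drugs. Without robust dispersion the mean of both drugs had 0 and any difference 2. camera with an estimated correlation gave 0 lists in OGD vs Control, OGD+CX-4945 vs OGD, OGD+MS-275 vs OGD, OGD+CX-4945 vs Control and the mean of both drugs.

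The samples were not treated as paired by the first 3 digits of the title numbers. Of 18 pairs of lanes of one set, 12 correlated above 0.1 in their deviations from the group mean, not all, and OGD+MS-275 lacks one set. The mean r was 0.190 within sets and -0.0953 between sets. By position of the title suffix 15 of 18 pairs did, again not all, with a mean r of 0.337, and -0.169 between positions. Lanes of one set or position were thus more alike on average, so a block structure is not excluded. The title-number block of 3 sets gave 24 in OGD+MS-275 vs OGD, 1 in OGD+CX-4945 vs Control, 37 in OGD+MS-275 vs Control, 18 for any difference, and 0 lists in OGD+MS-275 vs OGD and the mean of both drugs. The block of 2 sets gave 2, 9 and 2 for OGD+MS-275 vs OGD, OGD+MS-275 vs Control and any difference, and 0 lists in OGD+MS-275 vs OGD. The suffix-position block gave 3 in OGD+MS-275 vs OGD, 1 in OGD+CX-4945 vs Control, 33 in OGD+MS-275 vs Control, 3 for the mean of both drugs and 5 for any difference. With the ligation covariate 0 passed in OGD+MS-275 vs OGD, OGD+MS-275 vs Control, the mean of both drugs and any difference; lists were 2, 2, 1 and 2 in OGD+CX-4945 vs OGD, OGD+MS-275 vs Control, OGD+CX-4945 vs OGD+MS-275 and the mean of both drugs, and the MS-275 and OGD correlation was -0.302. Without the probes that lack a RefSeq gene those 4 counts were 0 and the correlation -0.290. Without the 2 lanes of lowest ligation counts the counts were 1 in OGD+CX-4945 vs OGD, 2 in OGD+MS-275 vs OGD, 9 in OGD+CX-4945 vs Control, 15 in OGD+MS-275 vs Control and 6 for any difference, with 0, 1 and 3 lists in OGD vs Control, OGD+CX-4945 vs Control and OGD+CX-4945 vs OGD+MS-275 and a CX-4945 and OGD correlation of -0.204.

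All reversals of values with a direction, with that shift taken off, came with the title-number block and ligation covariate together. Without taking it off, the Dlk1-Dio3 median also turned sign when scaled by the ligation controls, to -0.01 in OGD+CX-4945 vs OGD, -0.18 in OGD+MS-275 vs OGD, -0.07 in OGD+CX-4945 vs Control and -0.11 for the mean of both drugs. With the block and covariate 0 passed in OGD+MS-275 vs OGD, OGD+MS-275 vs Control, the mean of both drugs and any difference, lists were 0, 0, 0, 1, 1 and 0 in OGD+CX-4945 vs OGD, OGD+MS-275 vs OGD, OGD+CX-4945 vs Control, OGD+MS-275 vs Control, OGD+CX-4945 vs OGD+MS-275 and the mean of both drugs, and the correlations of MS-275 with OGD and of both drugs were -0.0291 and 0.670. In OGD+CX-4945 vs OGD miR-27a had 0.026, miR-410 -0.0090, miR-376a -0.075 and miR-376b -0.014. In OGD+MS-275 vs OGD miR-27a had 0.079, miR-99a 0.067, miR-30c 0.14, miR-376b -0.11, miR-22 0.067, miR-487b -0.28, let-7d 0.050, miR-15a 0.023, miR-190 0.13 and the Dlk1-Dio3 list -0.16. That list had -0.072 in OGD+CX-4945 vs Control and -0.089 for the mean of both drugs, where miR-27a had 0.053 and miR-99a 0.057, and miR-99a had 0.066 in OGD+MS-275 vs Control.

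With 1 sample left out in turn, calls ranged from 0 to 0 in OGD vs Control and in OGD+CX-4945 vs OGD+MS-275, 0 to 1 in OGD+CX-4945 vs OGD (1 without OGD+CX-4945 replicate 1), 0 to 1 in OGD+MS-275 vs OGD (0 without OGD replicate 1 or 2 or OGD+MS-275 replicate 2 or 3, miR-2141 in place of miR-2133 without OGD+MS-275 replicate 1), 0 to 6 in OGD+CX-4945 vs Control (6 without OGD+CX-4945 replicate 1, 1 without Control replicate 2) and 0 to 2 in OGD+MS-275 vs Control (2 others, miR-2140 and miR-2141, without OGD+MS-275 replicate 1, otherwise 0). They ranged from 0 to 11 for the mean of both drugs (11 without OGD+CX-4945 replicate 1, otherwise 0) and 0 to 4 for any difference (4 without OGD+CX-4945 replicate 1, 2 without OGD replicate 3 or OGD+CX-4945 replicate 3, otherwise 0). Lists ranged from 0 to 1 in OGD vs Control (0 without Control replicate 2 or OGD replicate 2 or 3), 0 to 1 in OGD+CX-4945 vs OGD (0 without OGD replicate 3 or OGD+CX-4945 replicate 2), 0 to 1 in OGD+MS-275 vs OGD (0 without OGD replicate 3 or OGD+MS-275 replicate 1 or 3), 0 to 1 for the mean of both drugs (0 without OGD replicate 3), and 0 to 3 in OGD+CX-4945 vs Control (3 without Control replicate 1, 0 without Control replicate 2 or 3 or OGD+CX-4945 replicate 2, 1 without OGD+CX-4945 replicate 1 or 3). They ranged from 0 to 2 in OGD+MS-275 vs Control (1 without Control replicate 1, 2 without OGD+MS-275 replicate 2) and 0 to 3 in OGD+CX-4945 vs OGD+MS-275 (3 without OGD+CX-4945 replicate 1, 2 without OGD+CX-4945 replicate 2 or OGD+MS-275 replicate 2). The correlations ranged from -0.557 to -0.239 for CX-4945 and OGD, -0.435 to -0.0370 for MS-275 and OGD, and 0.587 to 0.881 for both drugs.

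Shifts above 0.1 in the median log2 fold change of all probes were these. Scaling by the positive controls moved it by 0.36 in OGD+CX-4945 vs OGD, 0.43 in OGD+MS-275 vs OGD, 0.26 in OGD+CX-4945 vs Control, 0.34 in OGD+MS-275 vs Control and 0.38 for the mean of both drugs. Scaling by the mRNA probes moved it by -0.12 in OGD vs Control, 0.23 in OGD+CX-4945 vs OGD, 0.51 in OGD+MS-275 vs OGD, 0.13 in OGD+CX-4945 vs Control, 0.37 in OGD+MS-275 vs Control, -0.24 in OGD+CX-4945 vs OGD+MS-275 and 0.35 for the mean of both drugs. Scaling by the ligation controls moved it by -0.29 in OGD+CX-4945 vs OGD, -0.46 in OGD+MS-275 vs OGD, -0.21 in OGD+CX-4945 vs Control, -0.38 in OGD+MS-275 vs Control, 0.17 in OGD+CX-4945 vs OGD+MS-275 and -0.38 for the mean of both drugs. No filter moved it by 0.11 in OGD+MS-275 vs OGD. Background subtraction moved it by 0.17 in OGD+MS-275 vs OGD and 0.11 for the mean of both drugs. The deposited processed values moved it by -0.35 in OGD vs Control, 0.46 in OGD+CX-4945 vs OGD, 0.68 in OGD+MS-275 vs OGD, 0.10 in OGD+CX-4945 vs Control, 0.30 in OGD+MS-275 vs Control, -0.19 in OGD+CX-4945 vs OGD+MS-275 and 0.54 for the mean of both drugs.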

Other observations

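The set of the 13 probes without a RefSeq gene and the tests of the Dlk1-Dio3 list with the ligation covariate and the neuron list, and of the erythroid list with the ligation covariate were chosen only after the results were seen; the tests of the deposited values and of other splits were written before. The 13 tested probes with no RefSeq gene of their name, miR-2133, miR-2134, miR-2140 and miR-2141 among them, had a median log2 fold change of 0.43 in OGD+MS-275 vs OGD, with 10 of 13 higher. The set was formed after these 4 were seen to move, so no test of it is given. With the ligation covariate the median was 0.12. Over all probes, 25 were associated with the ligation count within groups, 10 higher and 15 lower at higher counts.

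Against Control, MS-275 nerves had higher means of miR-195 (61.1 ± 9.70 against 30.7 ± 14.6) and miR-103 (1022 ± 56.2 against 651 ± 112), both called by DESeq2 and not by edgeR. The leukocyte and inflammation miRNA miR-146b had 30.0 ± 3.30 normalised counts in Control, 45.5 ± 11.9 in OGD, 37.6 ± 6.67 in OGD+CX-4945 and 46.5 ± 9.11 in OGD+MS-275, and the mesenchymal miR-199a-3p 786 ± 137, 742 ± 144, 681 ± 169 and 534 ± 46.6. These miRNAs were named after their values were seen. Within groups, miR-103 rose and miR-199a-3p fell with the ligation count (edgeR adjusted p under 0.05 for each slope). The slopes of miR-195 and miR-146b did not pass. The mean background limits were 33.1 counts in Control, 51.1 in OGD, 53.8 in OGD+CX-4945 and 46.7 in OGD+MS-275. miR-146b in every group and miR-195 in Control lay near or below them.

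A first hypothesis was that ligation yield or a larger share of neuronal RNA accounts for the higher Dlk1-Dio3 list in both drug groups. With the ligation covariate its median, mean of both drugs vs OGD, was 0.33 against 0.29 without, and with the title-number block as well it was -0.09, so the corrections point in opposite directions. Lane values of the Dlk1-Dio3 and neuron lists, with group means removed, correlated (Pearson r = 0.838, permutation p = 5.5e-04; Spearman rho = 0.776, permutation p = 0.00411; r = 0.611 without the 2 farthest lanes; Benjamini-Hochberg value 0.0011 over 6 relations). The neuron list itself had medians of 0.197 with CX-4945, under the 0.2 asked for, and 0.29 with MS-275. By lane, as the difference from the Control mean, it was 0.33 in OGD+CX-4945 replicate 2, and -0.18 and -0.17 in replicates 1 and 3, below every OGD lane, so the value with CX-4945 rests on 1 lane. Neither explanation can be told apart from an effect of the drugs: the 2 ligation corrections disagree, and lists that vary together within groups may do so for reasons other than cell content.

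A further hypothesis was that ligation yield accounts for the lower erythroid list. In OGD+CX-4945 vs Control its median was -0.43 with the ligation covariate against -0.53 without, still below 0 but not past the threshold. In OGD vs Control it was -0.47 against -0.48 without, and past the threshold with the covariate (camera adjusted p = 0.0306). Whether ligation yield accounts for a part of the value in OGD+CX-4945 cannot be told on 3 miRNAs, and a different amount of blood left in the nerves was not tested.

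In the deposited processed values the median probe was lower in OGD than in Control (-0.33) and higher with the drugs than in OGD (0.49 with CX-4945, 0.71 with MS-275). Without OGD replicate 2, whose deposited values sum to 183249 against 284068 or more in the other lanes, these medians were 0.13, -0.02 and 0.20. That lane accounts for most of the shift, and the remaining 0.20 lies between the bounds set for it alone and for other causes. The ratio of miRNA to mRNA counts and the ligation count, with group means removed, had r = 0.513 (permutation p = 0.0850; Spearman rho = 0.441, permutation p = 0.152; r = 0.265 without the 2 farthest lanes; Benjamini-Hochberg value 0.0850 over 6 relations), so a part of ligation yield in it cannot be told apart from spread.

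Log2 ligation counts also correlated with log2 total miRNA counts (Pearson r = 0.809, permutation p = 0.00127; Spearman rho = 0.769, permutation p = 0.0049; r = 0.653 without the 2 farthest lanes; Benjamini-Hochberg value 0.0019). With group means removed r was 0.727 (permutation p = 0.00864), rho 0.678 (permutation p = 0.0185), r without the 2 farthest lanes 0.604 and the Benjamini-Hochberg value 0.0104.

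Other splits of the samples were refitted. 3 samples against 3 make 10 splits, too few for a share under 0.05. OGD vs Control gave 12 probes with an unadjusted p under 0.05 and the highest other split 24 (3 of 10 splits gave as many); OGD+CX-4945 vs OGD gave 16 and 60 (4 of 10); OGD+MS-275 vs OGD 45 and 25 (1 of 10); OGD+CX-4945 vs Control 18 and 45 (3 of 10); OGD+MS-275 vs Control 50 and 22 (1 of 10); OGD+CX-4945 vs OGD+MS-275 9 and 35 (7 of 10). By calls, OGD+MS-275 vs OGD gave 1 and the highest other split 0 (1 of 10), and OGD+MS-275 vs Control 3 and 0 (1 of 10). The split with 60 set OGD replicates 1 and 2 with OGD+CX-4945 replicate 1, and the one with 45 set Control replicates 1 and 2 with OGD+CX-4945 replicate 1, which points to a structure of the samples other than their groups. These lanes had the lower ligation counts of the 6 in each comparison.

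For the mean of both drugs vs OGD, 8 of 84 splits gave at least its 35 probes with an unadjusted p under 0.05 (highest other 75), and 9 of 84 at least its 1 call (highest other 47). For any difference among the 4 groups, 12 of 100 splits gave at least its 33 (highest other 82) and 7 of 100 at least its 1 call (highest other 37). Chance is not excluded for either result, and splits with many times the real calls point to a structure of the samples.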
